A study of Mus musculus with 7 samples.

How the data were processed

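The 7 RNA sequencing libraries of wild-type C57BL/6 mouse B cells each stood for 1 condition: unstimulated at 0 h, and anti-IgM, BAFF or both at 8 h and 30 h. No library was cultured without a stimulus, so time in culture could not be separated from stimulus. Per the submitters' processing notes, reads were processed with CASAVA 1.8.2, aligned to mm10 with TopHat2 2.0.5 and Bowtie2 2.0.0.7, and assembled with Cufflinks 2.0.2. The deposited values are FPKM of transcripts that Cufflinks assembled in each library separately, with a lower and an upper bound. The interval between them was read here as 2 standard deviations of counting error either way. A merged set of transcripts, per the submitters' processing notes, was used here for gene names, exons and gene positions, and has no expression values.

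Transcripts were given the gene name of the merged set by position and otherwise that of GENCODE release M21. Between 11009 and 11573 genes were named per library. FPKM was summed over the transcripts of a gene that had at least 300 bases, because shorter pieces made up 66.6% to 74.4% of the summed FPKM of a library. Mapped reads were recovered from FPKM, its interval and transcript length as 21.92 M (unstimulated), 28.61, 18.75 and 18.92 M (anti-IgM, BAFF and both at 8 h) and 23.13, 20.54 and 24.11 M (the same at 30 h). As a second measure, the reads of every assembled piece over the exons of a gene, on either strand, were divided by exon length and mapped reads. These reads were not counted but calculated back from the FPKM and length of each piece. The second measure is thus not independent of FPKM, and must nearly match it for a gene assembled alike in both libraries.

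A gene was compared when it was assembled in both libraries with an FPKM of at least 1 in 1 of them. It was counted as different when log2 of FPKM plus 1 differed by at least 1 and the intervals did not overlap. It was called held when the reads over exons differed by at least 1 the same way. The 13 comparisons were each stimulus against the unstimulated library, both stimuli against each single one, and 30 h against 8 h. No p-values were computed, because there were no replicates. The agreement of the effect of BAFF was computed for 3 pairs of comparisons without a shared library, and the combined stimulus was compared with the sum of the single effects on the log2 scale.

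The 38 gene lists were written from general knowledge, 30 of B cell biology and 8 of other cell types. The median difference of each was placed among 10000 lists of genes of similar expression, in 20 bins, with seed 7. The list of genes encoded by mitochondria could not be used, because it had 1 gene compared. Against the unstimulated library, the neutrophil, erythroid, platelet and stroma lists had 0 to 2 genes compared and were given no median. The same held for the NK cell list with BAFF at 30 h, with 2 genes compared.

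Named genes followed a rule: the 6 largest differences in each direction in the 6 main comparisons and the 3 largest in the others, at 5 FPKM or more and 300 bases or more, leaving out immunoglobulin segments, small RNAs and predicted genes, plus NF-kappaB, BAFF receptor, growth and survival genes named throughout and members of the fixed lists. Examples from the lists, and genes picked from the held sets and overlaps, were chosen after their values were seen.

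The steps were checked on simulated data with known differences. The simulated libraries had counting error only, with no separate assembly and no variation between samples. The rates below therefore do not cover those 2 sources of error. For anti-IgM at 8 h against the unstimulated library, with 11440 genes, 85.0% of genes made different by 1.5 and 94.0% of those made different by 2 were counted the right way, and 2 unchanged genes were counted. Of 200 lists of unchanged genes 7.5% lay outside the middle 95%, and 25 genes shifted by 0.5 gave a median of 0.52. For the agreement between the effect of BAFF beside anti-IgM at 8 h and at 30 h, with 11458 genes, unchanged differences had a correlation of -0.01. For the combined stimulus at 8 h against the sum, with 11458 genes and effects that add, 56 genes were counted.

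The alternatives planned before the values were seen covered the pseudocount, the filter on low values, the size of the difference, the intervals, 3 scalings, the most abundant transcript and gene length. The minimum of 300 bases, the reads over exons, the held genes, the spacing of 1000 bases, genes not assembled set to 0, the short pieces and the scalings of lists and named genes were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.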

Results

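After 8 h of antigen receptor stimulation, genes for making ribosomes, sterols and amino acids had higher FPKM than in the unstimulated library of mouse B cells. MHC class II genes and most genes of a quiescence and homing list had lower FPKM. Macrophage markers, whose cells carry class II, were lower too (median -2.20), and time in culture could not be separated from stimulus in that comparison. Class II was also lower with both stimuli than with BAFF alone at 8 h (median -0.64), where macrophage markers had a median of -0.04. BAFF alone went with higher values of the same anabolic groups, by smaller amounts. Nfkb2, Ltb and Il9r had higher values with BAFF than with anti-IgM, but the counting rule was not applied between these 2 stimuli. For Nfkb2 at 8 h that difference was under 2-fold. At 30 h the replication and mitosis genes were higher with every stimulus, BAFF alone included. Adding BAFF to anti-IgM left few gene differences that a second measure also showed. Each of the 7 conditions was 1 library, so no test between conditions was possible, and the intervals on FPKM cover counting error only.

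A gene was counted as different when it was assembled in both libraries, its FPKM differed at least 2-fold after adding 1, and its intervals did not overlap. It was called held when the reads over its exons, a second measure calculated from the same FPKM values, also differed at least 2-fold the same way. Being held is therefore not independent evidence of a difference. Median differences of gene lists are on the log2 scale and are placed among 10000 random lists of genes of similar expression, where percentile 0 or 100 means beyond nearly all of them. The median over all genes at 5 FPKM or more lay between -0.13 and 0.13 in every comparison.

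**Figure D1:**
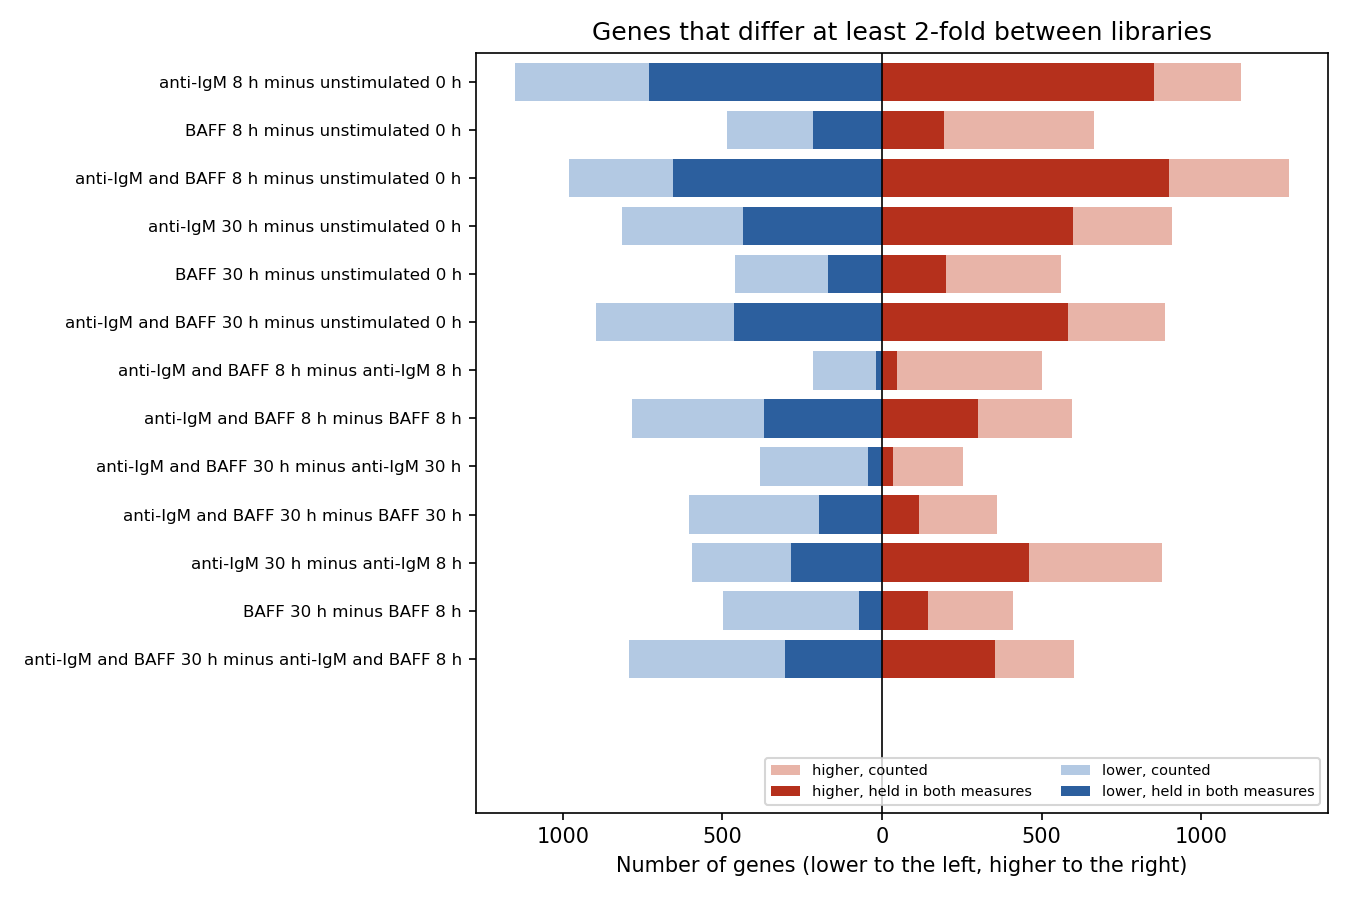
Numbers of genes counted as different in the 13 comparisons of single libraries, higher to the right and lower to the left; dark bars are the genes that also differed in the reads over exons. The dark bars are short where anti-IgM and BAFF is set against anti-IgM, 66 genes at 8 h and 78 genes at 30 h.

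Anti-IgM for 8 h went with higher RNA for most of the ribosome biogenesis genes listed. Of 27 ribosome biogenesis genes compared, 23 were higher, 0 lower and 4 not counted (median 1.72, percentile 100). Examples were Nop16 (15.0 FPKM unstimulated, 112 with anti-IgM) and Nhp2 (31.8, 178), which belong to pre-ribosome and small nucleolar RNA complexes, and Npm1 (496, 1519), a nucleolar chaperone. The 38 ribosomal protein genes compared had a median of -0.04 (percentile 21.66). Sterol and fatty acid synthesis had 15 higher, 1 lower and 9 not counted (median 2.04), with Idi1 (14.3, 142), an isoprenoid enzyme, Hmgcs1 (20.7, 128), the first committed step of the pathway, and Sqle (9.63, 57.6), squalene epoxidase. Amino acid and one-carbon genes had 18 higher, 0 lower and 5 not counted (median 1.59), led by Shmt2 (24.7, 151), a mitochondrial serine enzyme, and the amino acid transporter gene Slc7a5 (9.25, 64.1). Glycolysis had 10 higher, 1 lower and 8 not counted (median 1.06), including Ldha (111, 402), lactate dehydrogenase. Oxidative phosphorylation had a median of 0.65 with 4 of 25 counted, and heat shock genes had a median of 1.16, with Hspd1 (70.0, 335), a mitochondrial chaperonin, higher and Hspa1a (21.5, 1.19), an inducible chaperone, lower.

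The anti-IgM library at 8 h also had lower RNA for MHC class II, quiescence and homing, and B cell identity lists. MHC class II genes had 0 higher, 8 lower and 3 not counted (median -1.67, percentile 0), including H2-DMb2 (463, 29.8), a peptide-loading subunit, and Ciita (94.5, 13.8), the class II transactivator. Macrophages and dendritic cells also carry class II, and in the same comparison macrophage markers had a median of -2.20 (8 of 12 lower) and dendritic markers -0.55 (percentile 8.3). With BAFF at 8 h macrophage markers had a similar median (-2.24), but class II only -0.57. Both stimuli against BAFF at 8 h gave class II -0.64 and macrophage markers -0.04. Within these single libraries, this argues against macrophage loss or time in culture alone as the account of the larger class II difference with anti-IgM. Quiescence and homing genes had 2 higher, 15 lower and 5 not counted (median -1.15), with Klf2 (158, 18.8), a quiescence factor, and S1pr1 (77.6, 19.0), the receptor for egress from lymphoid tissue, lower and Ccr7 (114, 332), the receptor for homing to T cell zones, higher. B cell identity genes had 0 higher, 13 lower and 13 not counted (median -0.95), such as Cd22 (353, 50.8), an inhibitory coreceptor, and Pax5 (197, 47.6), the lineage factor. G1 and S control genes were mixed with a median of -0.66: Cdk4 (58.0, 209), a G1 kinase, was higher and Cdkn2d (27.1, 3.22), an inhibitor of it, lower. Among genes of early receptor signalling, 6 were higher and 9 lower, Egr2 (24.4, 67.2) against Fos (627, 3.69) and Egr1 (264, 61.6), all 3 immediate-early transcription factors.

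The largest differences at 8 h of anti-IgM were, upward, D4Ertd617e (2.19, 73.1), of unknown function, Tyms (4.42, 78.5), thymidylate synthase, Bcl2l1 (3, 53.3), which encodes BCL-XL, Ppil3 (0.971, 18.9), a cyclophilin, Idi1, and Mreg (9.56, 95.9), a melanosome transport regulator. Downward they were Fos, the linker histone gene Hist1h1c (96.7, 3.17), the transporter gene Abcg3 (41.0, 1.01), the RAP1 activator gene Rasgrp2 (248, 11.3), cyclin D3 (Ccnd3: 32.9, 0.790) and Rpl36 (763, 40.7), a ribosomal protein gene. Tyms was not held, and D4Ertd617e, Ccnd3 and Rpl36 have another expressed gene within 1000 bases, which can take reads from them. In all, 1124 genes were higher and 1150 lower of 10494 compared, and 853 and 729 of these were held.

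BAFF for 8 h went with higher RNA for the same sterol, ribosome and amino acid groups, at smaller medians than anti-IgM. Sterol synthesis had 12 higher, 0 lower and 13 not counted (median 0.99), with Idi1 at 78.4 and Hmgcs1 at 87.2 FPKM. Ribosome biogenesis had 4 higher, 0 lower and 23 not counted (median 0.80), 26 of its 27 members lying above 0, and amino acid and one-carbon genes had 7 higher, 0 lower and 16 not counted (median 0.73), with Shmt2 at 72.8. Early receptor genes had 2 higher, 13 lower and 7 not counted (median -1.15, percentile 0), including Egr1 (264 unstimulated, 14.7 with BAFF), Egr2 (24.4, 5.60), and Nr4a1 (350.5, 29.9), an orphan nuclear receptor induced by the antigen receptor. Fos was at 627 FPKM unstimulated and 7.22 or less in every cultured library, and with anti-IgM at 8 h the list had 6 higher and 9 lower. A fall with time in culture could thus not be told apart from an effect of BAFF. The NF-kappaB list had 6 higher, 1 lower and 16 not counted (median 0.32, percentile 98.26): Nfkb2 (75.3, 184), the p100 precursor of the alternative pathway, Relb (41.1, 101, not held), its partner, Bcl3 (23.6, 58.3), a nuclear cofactor of p52, and Traf1 (19.5, 50.5), a signalling adaptor, were among the higher.

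Genes described before as responsive to BAFF had a median of -0.59 with BAFF at 8 h (percentile 0.12), with 4 above 0 and 7 below. Of 11 compared, Pim2 (19.5, 135), a survival kinase, and Nfkb2 were higher, Cr2 (94.0, 31.8), complement receptor 2, and H2-DMb2 (463, 229.6) were lower, and 7 were not counted, including Bcl2l1 (3, 13.9), whose interval was wide, Fcer2a (333, 370.4), which encodes CD23, and Mcl1 (253, 167), an anti-apoptotic gene. The largest upward differences with BAFF at 8 h were Tyms (179 with BAFF), Ddah2 (3.89, 82.6), a dimethylarginine hydrolase, Ndufs1 (1.22, 33.5), a complex I subunit, Ppil3 (17.9 with BAFF), the chemokine gene Ccl22 (1.78, 25) and D4Ertd617e (26.0 with BAFF). The largest downward differences were Fos (7.22 with BAFF), Cbx3 (67.8, 0.955), a heterochromatin protein, the adhesion gene Vcam1 (48.6, 1.79), Egr1, Rps15a (2000, 126), a ribosomal protein gene, and Klf4 (36.1, 1.74), a quiescence factor. Tyms and Rps15a were not held, and Ddah2, Ndufs1, D4Ertd617e and Cbx3 have a close expressed neighbour. BAFF had 665 genes higher and 485 lower at 8 h, with 195 and 216 held.

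**Figure D2:**
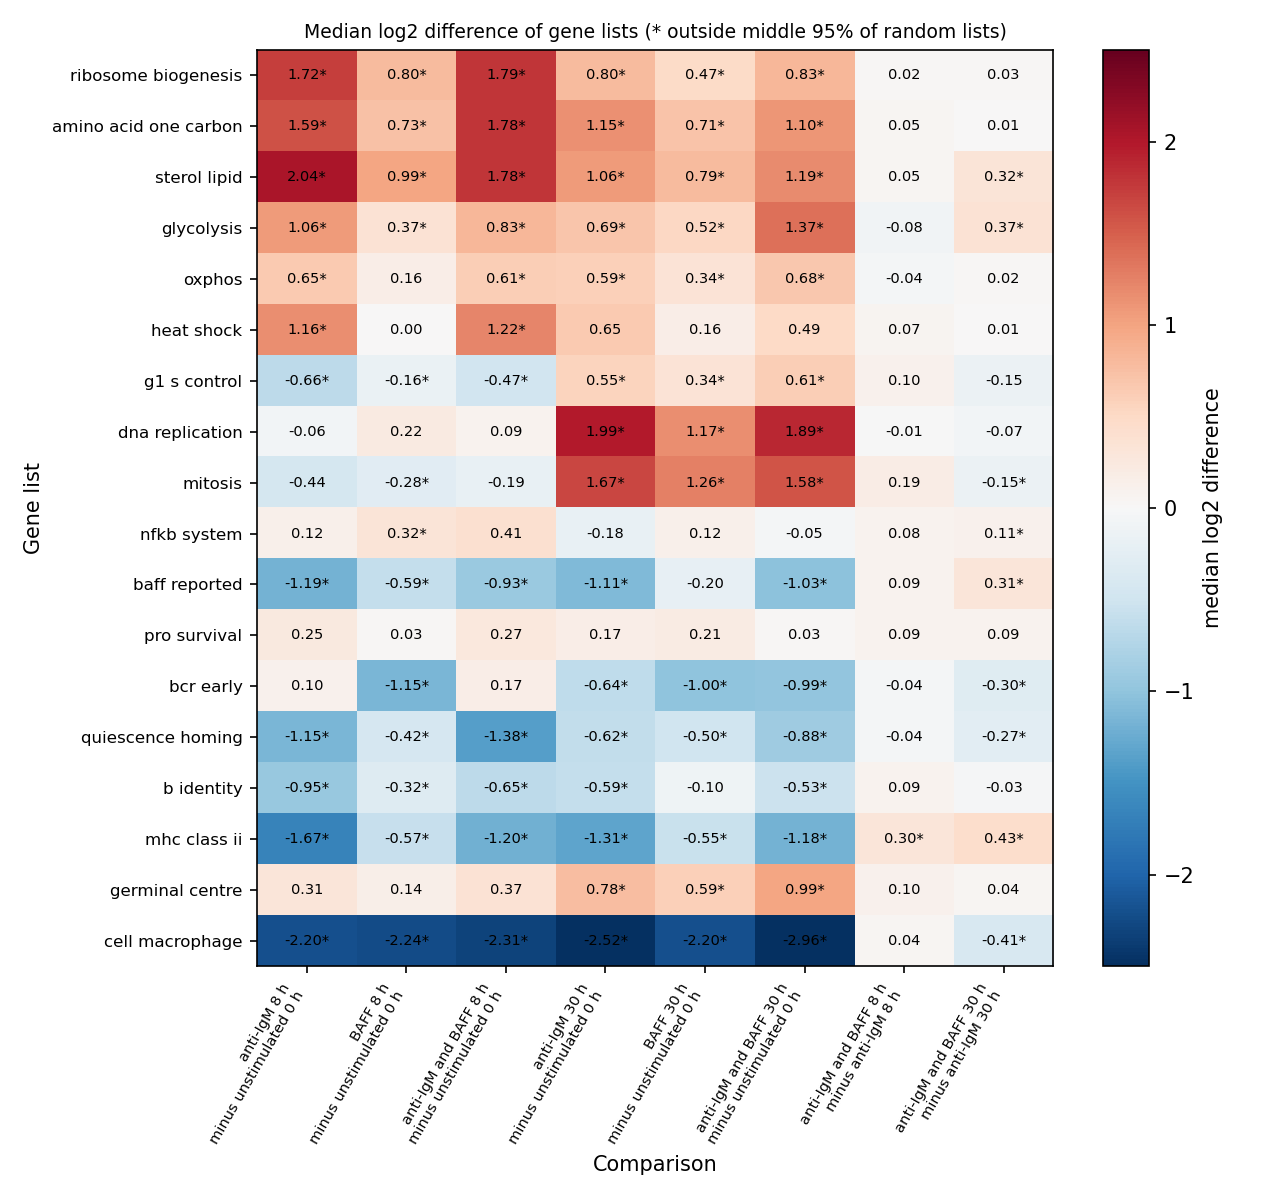
Median log2 difference of FPKM over the members of 18 gene lists (vertical) in 8 comparisons of single libraries (horizontal), with an asterisk where the median lay outside the middle 95% of random lists. The last 2 columns, which add BAFF to anti-IgM, lie between -0.41 and 0.43.

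At 30 h of anti-IgM the DNA replication and mitosis lists stood highest. DNA replication genes had 26 higher, 1 lower and 2 not counted (median 1.99, percentile 100), including Mcm6 (21.3 unstimulated, 129 with anti-IgM), a helicase subunit, Rrm2 (7.29, 57.1), which makes deoxynucleotides, and Lig1 (8.95, 62.8), the replicative ligase. Mitosis genes had 24 higher, 1 lower and 3 not counted (median 1.67), with Kif11 (3.38, 42.8), a spindle motor, Cdk1 (4.54, 40.5), the mitotic kinase, and Mki67 (5.60, 34.1), a proliferation marker. G1 and S control had 6 higher, 1 lower and 13 not counted (median 0.55), among them Ccnd2 (18.1, 66.2), cyclin D2, and E2f1 (4.09, 25.6), a factor for S phase entry. Germinal centre and switching genes had 5 higher, 1 lower and 5 not counted (median 0.78): Ung (4.63, 36.8), uracil glycosylase, and Mef2b (2.52, 20.5), a transcription factor, were higher, and Bcl6 (33.8, 7.70), the germinal centre repressor, was lower. Ribosome biogenesis (median 0.80, 7 of 27 higher), sterol synthesis (1.06, 13 of 25), amino acid and one-carbon genes (1.15, 15 of 23), glycolysis (0.69, 8 of 19) and oxidative phosphorylation (0.59, 5 of 26) were still above the unstimulated library. MHC class II (median -1.31, 6 of 11 lower), quiescence and homing (-0.62, 9 of 22 lower) and B cell identity (-0.59, 6 of 26 lower) were below it. So were markers of macrophages, which carry class II (-2.52, 9 of 14 lower).

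The largest upward differences at 30 h of anti-IgM were Ttll3 (2.42, 62.8), a tubulin-modifying ligase, Ndufs1 (32.7 with anti-IgM), Ccl22 (1.78, 40.8), the replication-coupled methylation factor gene Uhrf1 (7.55, 91.3), Cdc6 (1.21, 21.2), which licenses origins, and Kif11. The largest downward were Fos (627, 2.38), Jun (139, 3.44), its partner, the beta-globin gene Beta-s (218, 7.16), the chemokine receptor gene Cxcr4 (479, 19.4), Hist1h1c (96.7, 3.69) and the transferrin gene Trf (30.5, 0.767). Ndufs1 was not held, and Ttll3, Ndufs1 and Cdc6 have a close neighbour. In all 907 genes were higher and 814 lower, with 597 and 436 held.

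BAFF alone at 30 h also went with higher cell cycle genes. DNA replication genes had 19 higher, 1 lower and 8 not counted (median 1.17, percentile 100) and mitosis genes 16 higher, 1 lower and 11 not counted (median 1.26). Mcm6 was at 57.7 FPKM, Rrm2 at 30.7, Cdk1 at 25.5 and Mki67 at 19.3, each between the unstimulated and the anti-IgM value. Ccnd2 was at 26.5 and E2f1 at 6.93, above the unstimulated 18.1 and 4.09 but not counted, and the G1 and S control list had a median of 0.34 (percentile 98.88). Sterol synthesis (median 0.79, 9 of 24 higher) and amino acid and one-carbon genes (0.71, 3 of 23 higher and 1 lower) were above the unstimulated library, and so was ribosome biogenesis (0.47), where none of 27 genes was counted but 24 lay above 0. Early receptor genes had 0 higher, 11 lower and 11 not counted (median -1), and quiescence and homing genes 0 higher, 5 lower and 17 not counted (median -0.50). The early receptor medians at 30 h were also below 0 with anti-IgM (-0.64) and with both stimuli (-0.99).

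Some immune genes, mostly picked after their values were seen, had their highest value with BAFF alone at 30 h. They included Ltb (236 unstimulated, 479.7 with BAFF, 36.1 with anti-IgM), lymphotoxin beta, and Icosl (117, 156, 13.1), the ICOS ligand gene. Ccl22 (1.78, 103, 40.8) and Vpreb3 (37.1, 84.1, 12.8), a receptor-assembly factor, were also highest there. Against the unstimulated library Ccl22 was held, Ltb and Vpreb3 were counted but not held, and Icosl was not counted. As sets, cytokine and chemokine genes had a median of -0.13 (3 higher, 3 lower) and activation surface genes -0.21 (0 higher, 2 lower) there. MHC class II genes lay lower, with a median of -0.55, although H2-Ab1 (243, 707) was higher, and in the same comparison markers of macrophages, which carry class II, had a median of -2.20 (11 of 16 lower). The largest upward differences were Ccl22, Ttll3 (70.2 with BAFF), Ndufs1 (29.6), Snx22 (9.67, 121), a sorting nexin, the relaxin gene Rln3 (1.69, 23.9) and Amigo2 (3.56, 35.1), an adhesion protein gene. The largest downward were Fos (1.63 with BAFF), Beta-s (12.2), Nr4a1 (21.2), the iron exporter gene Slc40a1 (46.6, 2.12), Rhob (108, 6.54), a small GTPase gene, and Ppp1r15a (154, 10.5), a stress phosphatase subunit. Ndufs1 and Snx22 were not held, and Ttll3, Ndufs1, Snx22, Rln3, Amigo2 and Ppp1r15a have a close neighbour. BAFF had 560 genes higher and 460 lower at 30 h, with 201 and 170 held.

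Some NF-kappaB genes had different values with the 2 stimuli, which were not compared directly. Rel, which encodes c-Rel, was at 39.2 FPKM unstimulated, 140 and 114 with anti-IgM at 8 h and 30 h, and 85.6 and 48.9 with BAFF. Nfkb1, the p105 gene, had the same order (81.6 unstimulated; 189.6 and 151 with anti-IgM; 113 and 85.9 with BAFF). Nfkb2 was at 184 and 134 with BAFF, 147 and 66.1 with anti-IgM and 198 and 183 with both stimuli, so that at 30 h it stood at 66.1 without BAFF and 183 with it beside anti-IgM. Rela, the p65 gene, stayed between 40.0 and 57.9 in all 7 libraries. The inhibitor gene Nfkbia was at 112 unstimulated and highest with both stimuli at 8 h (218), and Nfkbie, another inhibitor gene, was assembled only with BAFF at 8 h (79.7), anti-IgM at 30 h (94.8) and BAFF at 30 h (46.7). The BAFF receptor gene Tnfrsf13c had its lowest value with BAFF at 8 h (48.8) and its highest with anti-IgM at 30 h (154). Tnfrsf13b, which encodes TACI, lay between 61.0 and 127.

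Values of single growth and survival genes are given here without a direct comparison of the 2 stimuli. Myc, a growth regulator, was at 143 unstimulated, 263 and 61.2 with anti-IgM at 8 h and 30 h, and 64.7 and 29.8 with BAFF. Bcl2l1 was at 53.3 and 33.1 with anti-IgM and 13.9 (interval 1.65 to 26.1) and 6.38 with BAFF, while Bcl2l11, which encodes the pro-apoptotic BIM, was at 16.0 unstimulated, 52.0 and 51.7 with anti-IgM and 21.9 and 15.6 with BAFF. Mcl1 was highest unstimulated (253). The BCL2-related gene Bcl2a1b was at 41.6 unstimulated and 164 with anti-IgM at 30 h, and its relative Bcl2a1d, not assembled in the unstimulated library, lay between 50.2 and 108 elsewhere. Ccnd3 was at 0.790 with anti-IgM at 8 h and at 46.9 and 45.9 with anti-IgM and BAFF at 30 h. Over the pro-survival list no comparison with the unstimulated library gave a median outside the random range, and 0.27 was the largest.

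**Figure D3:**
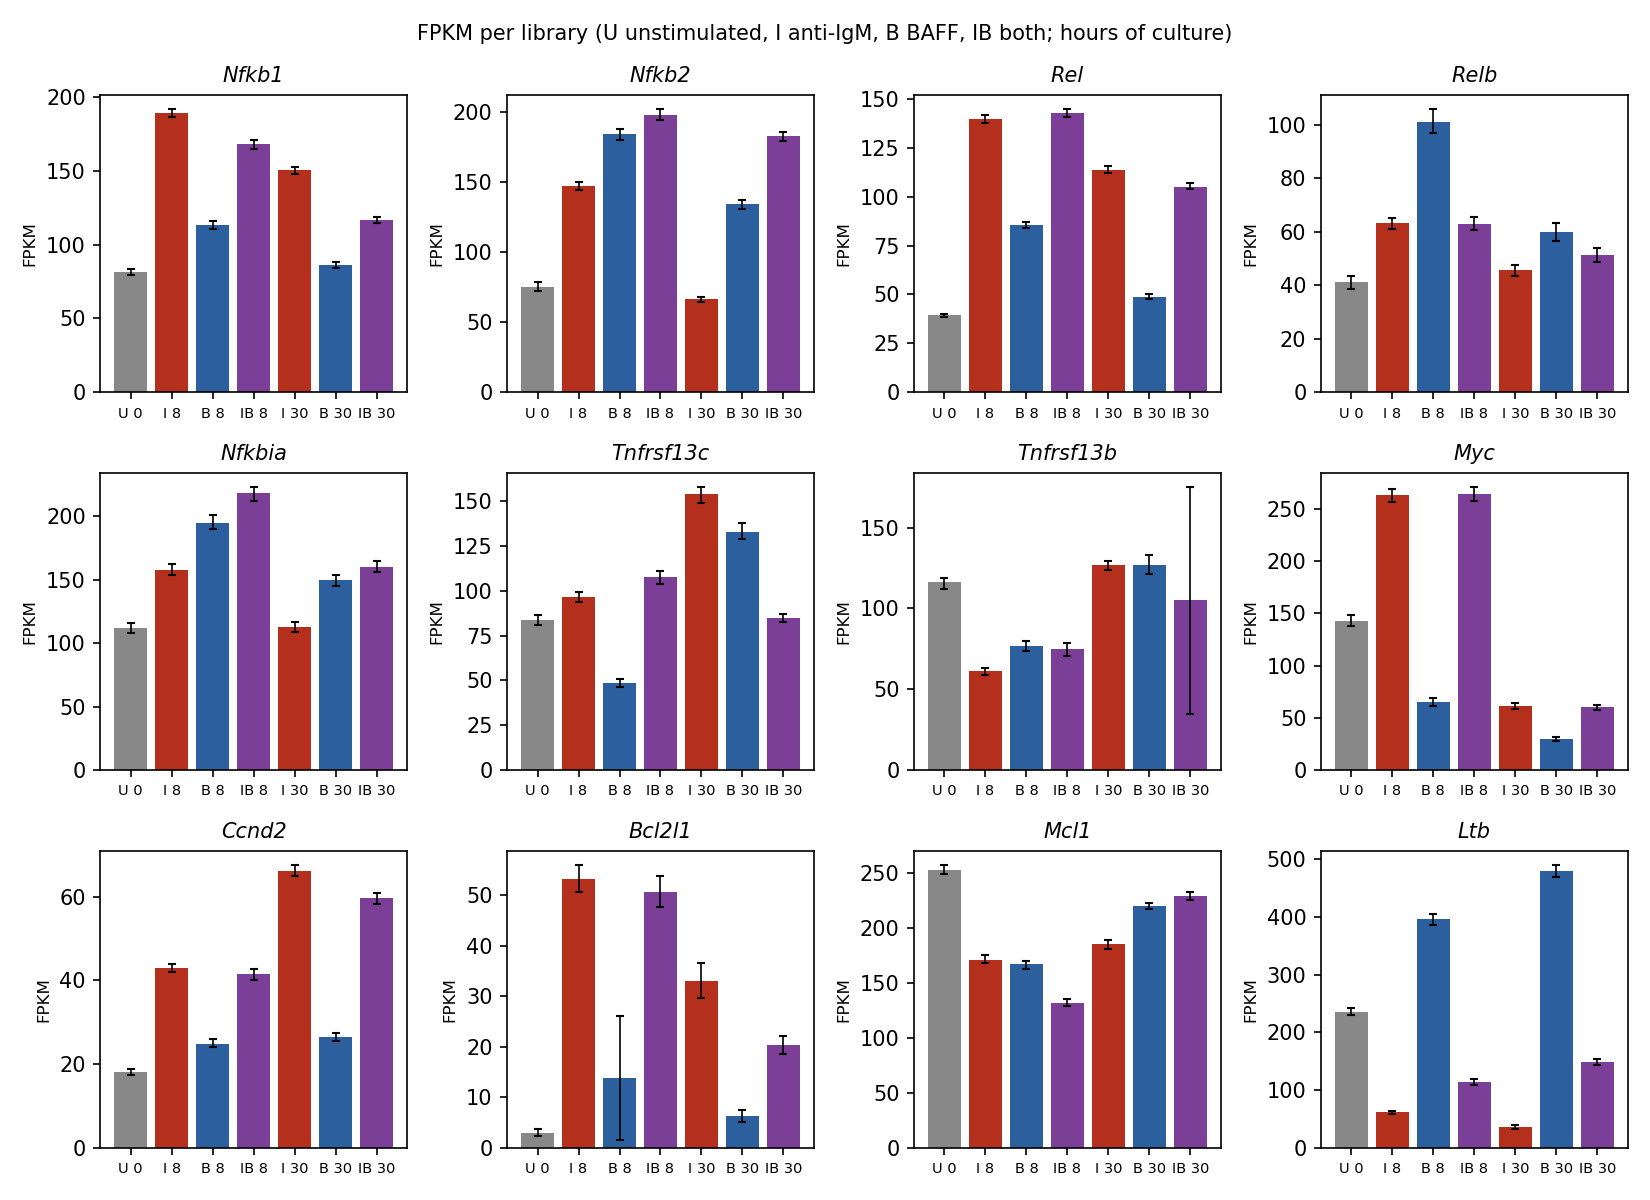
FPKM (vertical) of 12 genes in the 7 libraries (horizontal), 1 library per bar, with the interval of counting error of the deposited values. Nfkb2 and Ltb are higher with BAFF than with anti-IgM at both times, and Rel, Myc, Ccnd2 and Bcl2l1 are higher with anti-IgM.

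Adding BAFF to anti-IgM at 8 h went with higher MHC class II and otherwise with small list differences. The class II median was 0.30 (percentile 99.51): 1 gene, H2-DMb2 (29.8 with anti-IgM, 108 with both), was counted higher, 0 lower and 10 not counted, and 10 of 11 lay above 0. The early receptor (-0.04), NF-kappaB (0.08) and ribosome biogenesis (0.02) lists had medians inside the random range. Held genes with no close neighbour included Il9r (7.07, 20.1), a cytokine receptor chain, Ndufb8 (18.4, 75.5), a complex I subunit, and Ffar1 (54.6, 7.54), a fatty acid receptor, which was lower. These and other examples of held genes in this comparison were chosen after their values were seen.

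The largest differences by the fixed rule were mostly uncertain here. Upward they were Rpl36 (40.7, 942), Timm8b (4.62, 75.6), a mitochondrial import factor, Ccnd3 (0.790, 12.9), Fut11 (3.47, 32.0), a fucosyltransferase, Psenen (17.6, 136), a gamma-secretase subunit, and AC121821.1 (7.77, 49.3), an unnamed locus. Downward they were Tyms (78.5, 5.49), Cntf (22.7, 1.17), a neurotrophic factor gene, Atp5g2 (415, 47.1), an ATP synthase subunit, H2-Q4 (235, 31.1), a class I gene, Minos1 (122, 17.1), a mitochondrial cristae protein, and Ffar1. Timm8b, AC121821.1, Tyms and Minos1 were not held, and all 6 upward genes, Cntf and H2-Q4 have a close neighbour. Of 500 genes higher and 215 lower, 47 and 19 were held.

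At 30 h, the medians of glycolysis, sterol and MHC class II genes were higher with BAFF beside anti-IgM than without it, while almost none of their members was counted. Glycolysis had 0 of 20 genes counted but a median of 0.37 (percentile 100), with 19 of 20 above 0, such as Gapdh (816 with anti-IgM, 1218 with both), Eno1 (183, 305), enolase, and Tpi1 (111, 209.8), triosephosphate isomerase. Sterol synthesis had a median of 0.32 (percentile 100, 1 of 25 counted), MHC class II 0.43 (percentile 99.98, 0 of 11 counted), hypoxia genes 0.24 and the genes described before as BAFF-responsive 0.31, where Nfkb2 was the counted gene. Early receptor genes (median -0.30, 2 of 22 counted and 0 held), quiescence and homing genes (-0.27, 1 of 22 counted) and mitosis genes (-0.15, 0 of 28 counted, random bound -0.14) lay lower, as did macrophage markers (-0.41, percentile 0.14). Oxidative phosphorylation (0.02) and amino acid and one-carbon genes (0.01) lay inside the random range. Lower values were seen for Egr2 (82.4, 60.3), Dusp2 (119, 67.3), a MAP kinase phosphatase, S1pr1 (20.8, 9.48) and Cdk1 (40.5, 35.9). Pim2 was at 65.7 and 93.9, Bcl2l1 at 33.1 and 20.4 and Bcl2l11 at 51.7 and 31.2.

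The largest upward differences at 30 h from adding BAFF were Cd68 (14.8, 189.9), a lysosomal protein gene, Ppil3 (0.891, 20.5), Il9r (4.90, 31.3), Ndufb8 (17.1, 92.6), Ifi27l2a (53.2, 274), an interferon-inducible gene, and Sod1 (38.0, 179), superoxide dismutase. All 6 were held, and only Cd68 has a close neighbour. Ltb (36.1, 149) was held as well. The largest downward were Ptpn18 (209.6, 24.3), a phosphatase, Anapc13 (70.5, 7.70), an anaphase-promoting complex subunit, Snn (348, 45.4), a small membrane protein, AI428936 (10.4, 1.08), Ccl25 (10.2, 1.07), a chemokine gene, and Eif2c3 (14.3, 2.03), an Argonaute gene. All 6 have a close neighbour, and Ptpn18, Ccl25 and Eif2c3 were not held. In all 253 genes were higher and 381 lower, with 33 and 45 held.

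Adding anti-IgM to BAFF gave the larger differences of the 2 additions. At 8 h, ribosome biogenesis (median 1.09, 16 of 27 higher), amino acid and one-carbon genes (1.00, 12 of 23), heat shock genes (1.05, 6 of 10) and early receptor genes (0.90, 10 of 22) were higher with both stimuli than with BAFF alone. Quiescence and homing (-0.58, 9 of 22 lower), B cell identity (-0.61, 7 of 26) and MHC class II (-0.64, 4 of 11) were lower. The largest differences were Cd68 (9.25 with BAFF, 329 with both), Cbx3 (0.955, 58.9) and Egr2 (5.60, 70.2) upward and Tyms (179, 5.49), Ddah2 (82.6, 2.21) and Tbx6 (38.7, 1.49), a T-box factor gene, downward. Tyms was not held, and Cd68, Cbx3, Ddah2 and Tbx6 have a close neighbour. Of 596 genes higher and 782 lower, 299 and 369 were held.

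At 30 h DNA replication genes were higher with both stimuli than with BAFF (median 0.80, 5 of 28 counted, all 28 above 0), as were glycolysis genes (0.68, 4 of 19). B cell identity (-0.56, 5 of 26 lower), MHC class II (-0.68, 2 of 10 lower) and Ltb (479.7, 149) were lower. The largest differences were Cd68 (7.31, 189.9), Aoc2 (4.35, 42.3), an amine oxidase, and Rasd1 (1.08, 15.2), a RAS-like GTPase gene, upward and Erp27 (181, 0.774), an endoplasmic reticulum protein, Prr7 (34.9, 1.71), a membrane adaptor, and Anapc13 (112, 7.70) downward. Erp27 was at 5.22 or less in the other libraries, and the other 5 genes have a close neighbour. Of 361 genes higher and 604 lower, 116 and 196 were held.

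Set against the unstimulated library, both stimuli together resembled anti-IgM. At 8 h all 27 ribosome biogenesis genes were higher (median 1.79), with 16 higher and 1 lower of 25 sterol genes (1.78) and 0 higher and 8 lower of 11 class II genes (-1.20). Markers of macrophages, which carry class II, had a median of -2.31 there (9 of 13 lower). At 30 h 26 of 29 replication genes were higher (1.89), and glycolysis had its highest median of any comparison (1.37, 10 of 19). The largest differences at 8 h were D4Ertd617e (2.19, 50.1), Bcl2l1 (3, 50.7) and Ndufs1 (1.22, 25.3, not held) upward and Fos (627, 2.5), Fosb (86.1, 1.52), its relative, and Hist1h1c (96.7, 2.03) downward. At 30 h they were Ccl22 (1.78, 68.3), Amigo2 (3.56, 49.9) and Ppil3 (0.971, 20.5) upward and Fos (627, 1.28), Hes1 (71.8, 1.43), a Notch target, and Cxcr4 (479, 15.2) downward. The counts were 1274 higher and 980 lower at 8 h (899 and 656 held) and 887 and 897 at 30 h (582 and 464 held).

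In the anti-IgM libraries, ribosome biogenesis and sterol genes were lower at 30 h than at 8 h and cell cycle genes higher. Ribosome biogenesis had 0 higher, 15 lower and 12 not counted (median -1.10), and sterol synthesis 1 higher, 9 lower and 15 not counted (-0.88). Ribosomal protein genes lay the other way (0.39, percentile 99.08, 30 of 38 above 0), and oxidative phosphorylation (0.10) and glycolysis (-0.14) lay inside the random range. DNA replication had 24 higher, 1 lower and 4 not counted (1.92), mitosis 17 higher, 0 lower and 7 not counted (1.93), and B cell identity 6 higher, 0 lower and 20 not counted (0.52). Interferon genes had a median of -0.51 (9 of 25 lower), for example Isg15 (45.2 at 8 h, 16.2 at 30 h). The largest differences were Ttll3 (1.01, 62.8), Ccnd3 (0.790, 46.9) and Ptpn18 (6.97, 209.6) upward, all with close neighbours, and Cd68 (321, 14.8), Vegfa (31.4, 0.975), an angiogenic factor gene, and Ppil3 (18.9, 0.891) downward. The counts were 876 higher and 596 lower, with 459 and 286 held.

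With BAFF, mitosis genes had 17 higher, 0 lower and 10 not counted at 30 h against 8 h (median 1.36) and replication genes 12 higher, 1 lower and 14 not counted (0.96). NF-kappaB genes had 0 higher, 1 lower and 23 not counted (-0.39, percentile 0.01), with Rel at 85.6 and 48.9 and Relb at 101 and 60.1. The largest differences were Cbx3 (0.955, 68.1), Erp27 (5.22, 181) and Snx22 (9.77, 121) upward and Ddah2 (82.6, 5.31), Tyms (179, 15.1) and Tbx6 (38.7, 3.34) downward, where Snx22 and Tyms were not held and Cbx3, Snx22, Ddah2 and Tbx6 have a close neighbour. Of 409 genes higher and 497 lower, 143 and 71 were held. With both stimuli, 602 genes were higher and 793 lower (353 and 304 held). The largest were Kif11 (2.33 at 8 h, 37.6 at 30 h), Pld4 (9.93, 97.2), an exonuclease gene, and Mki67 (2.61, 30.4) upward, and Anapc13 (121, 7.70), Tesk1 (37.9, 2.53), a kinase gene, and Snn (373, 45.4) downward, these last 3 with close neighbours and Tesk1 not held.

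Few genes were counted the same way for BAFF beside anti-IgM at 8 h, at 30 h and for BAFF alone, though more than independent lists would share. Genes counted in opposite directions also outnumbered those of independent lists, so the excess is not agreement alone. Il9r was the only gene held higher in all 4 of these comparisons, by 1.38 and 2.46 beside anti-IgM and by 2.29 and 2.23 alone at 8 h and 30 h. The Pearson correlation over 10091 genes was 0.03 between the 2 times, and 0.14 in the reads over exons. The counted genes shared were 27 higher and 14 lower, where independent lists of the same sizes share 10.2 and 6.4, and 56 were counted in opposite directions (independent lists 19.3). After the second measure 4 higher and 1 lower remained (independent lists 0.1 each), namely Il9r, Ndufb8 and the ribosomal protein genes Rpl36 and Rpl7a, and the zinc finger gene Zfp296. In opposite directions 3 remained (independent lists 0.2). BAFF alone and BAFF beside anti-IgM had a correlation of 0.02 at 8 h (47 higher, 19 lower and 51 opposite, independent lists 27.7, 7.9 and 30.4) and 0.03 at 30 h (36, 21 and 45, independent lists 11.8, 12.6 and 25.7). Held in these pairs were Il9r and Ndufb8 higher and Ffar1, Tstd1, a thiosulfate enzyme gene, and Zfp668, a zinc finger gene, lower at 8 h. At 30 h Ifi27l2a, Il9r, the splicing gene Snrnp25 and the predicted gene Gm10800 were higher, and the chemokine genes Ccl3 and Ccl4, the urokinase receptor gene Plaur and 2 overlapping lambda light chain segments (Iglc3 and Iglj3) were lower. Held genes in opposite directions numbered 3 at 8 h, against 5 the same way, and 8 at 30 h, against 9 the same way (opposite in independent lists 1.1 and 1.2). No library is shared within these 3 pairs, and the names of genes in these overlaps were taken from the counts and not from the fixed rule.

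The combined stimulus was also set against the sum of the single effects on the log2 scale. Below the sum lay genes that either stimulus alone had already brought up, such as Ccl22 (12 and 25 alone, 15.7 together at 8 h), D4Ertd617e (73.1, 26.0, 50.1) and Dtx4 (17.2, 18.3, 13.6), a ubiquitin ligase gene. Above the sum lay genes that each stimulus alone had low, such as Fos (3.69, 7.22, 2.5) and Klf4 (1.61, 1.74, 3.16). At 8 h 848 genes were above and 806 below the sum (245 and 224 held) and at 30 h 569 above and 877 below (138 and 280 held). Of the 245 held above at 8 h, 125 were at least 2-fold lower with each single stimulus, and of the 224 held below, 124 were at least 2-fold higher with each. At 30 h these were 94 of 138 and 144 of 280. A gene that every cultured library has at the same level above or below the 0 h library departs from the sum by construction.

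Markers of other cells differed with culture. Macrophage genes had medians between -2.20 and -2.96 against the unstimulated library in the 6 comparisons. They included the complement gene C1qa (40.3 unstimulated, 5.08 or less in culture), Hmox1 (95.2, 12.8 or less), haem oxygenase, and Slc40a1 (46.6, 4.80 or less). Of 52 markers of other cell types at 1 FPKM or more in some library, 18 were at that level in all 7, such as Lck, Cd2, Cst3 and Pecam1. The macrophage list gave 9 of these 18. B cells and other cells left in the cultures cannot be told apart as their source. Vcam1 and Slc40a1, named above with BAFF, and Cd68 are also on the macrophage list. The beta-globin gene Beta-s, named above among the largest downward differences at 30 h, was not on the erythroid list. That list has beta-globin genes under other names, and 1 of its 12 members reached 1 FPKM in some library. Whether the lower Beta-s values came from erythroid RNA lost in culture was not tested.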

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

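In 4 pairs of list and stimulus, the median lay below the random range against the unstimulated library at 8 h and above it at 30 h. The G1 and S control list, with cyclins, their kinases and inhibitors, had a median of -0.66 at 8 h and 0.55 at 30 h with anti-IgM, a difference of 1.21. With BAFF the medians were -0.16 and 0.34 (difference 0.50) and with both stimuli -0.47 and 0.61 (difference 1.08). The mitosis list had -0.28 at 8 h and 1.26 at 30 h with BAFF, a difference of 1.54. The mitosis list with anti-IgM (-0.44, then 1.67) and both (-0.19, then 1.58) and the DNA replication list with anti-IgM (-0.06, then 1.99) had the same signs, but at 8 h they lay inside the random range. These 4 were singled out because both medians lay outside the random range with opposite signs, a rule chosen after the values were seen, and the differences between times were not tested.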

How the results depend on the processing

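The counts moved most with the size of the difference required, with genes not assembled set to 0 and with the second measure, and the cause was not tested except for the genes not held when BAFF was added at 8 h. Counts are given in the order anti-IgM, BAFF and both at 8 h, then at 30 h, against the unstimulated library; both against anti-IgM and against BAFF at 8 h, then at 30 h; and 30 h against 8 h for anti-IgM, BAFF and both. With a difference of at least 0.6 they were 4383, 2709, 4282, 3776, 2385, 3841, 1664, 3227, 1579, 2415, 3293, 2144 and 3186. With at least 2 they were 348, 147, 332, 265, 121, 243, 43, 96, 42, 71, 169, 80 and 125. With genes not assembled set to 0 they were 3989, 2651, 4040, 3354, 2438, 3384, 1676, 2648, 1506, 2019, 2709, 2023 and 2688. Held genes with no expressed gene nearby were 975, 274, 954, 671, 229, 678, 29, 405, 31, 195, 436, 119 and 392. Genes held in both measures were 1582, 411, 1555, 1033, 371, 1046, 66, 668, 78, 312, 745, 214 and 657. Adding BAFF to anti-IgM, the most abundant transcript gave 385 genes at 8 h and 356 at 30 h, and the reads over exons 373 at each time.

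For the effect of BAFF, a difference of at least 0.6 gave 127 genes higher and 69 lower in both comparisons between the 2 times, 217 and 76 between BAFF alone and beside anti-IgM at 8 h, and 132 and 133 at 30 h. Held genes were 4 and 1, 2 and 3, and 4 and 5. Held genes off the sum of the single effects were 469 at 8 h and 418 at 30 h.

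The balance of higher and lower genes depended on scaling, measure, the difference required and genes not assembled, and is not a result. Against the unstimulated library, a difference of at least 2 gave, among others, 68 higher and 79 lower for BAFF at 8 h and 45 and 76 at 30 h. Genes not assembled set to 0 gave, among others, 1274 and 1377 for BAFF and 1908 and 2132 for both at 8 h. Scaling each library to the same summed FPKM gave 826 higher and 1341 lower for anti-IgM at 8 h, 643 and 1513 for both at 8 h, 522 and 1257 for anti-IgM at 30 h, 256 and 747 for BAFF at 30 h and 318 and 1913 for both at 30 h, against the unstimulated library. Both against anti-IgM had 291 and 292 at 8 h and 119 and 446 at 30 h, and both against BAFF 210 and 1326, and 179 and 738. From 8 h to 30 h it gave 594 and 750 for anti-IgM, 176 and 854 for BAFF and 390 and 913 for both. Leaving out immunoglobulin genes gave 1091 and 1091 for both at 8 h, 685 and 1042 for anti-IgM, 456 and 537 for BAFF and 606 and 1239 for both at 30 h, 256 and 717 for both against BAFF at 30 h, and 664 and 838 for anti-IgM from 8 h to 30 h. Median-ratio scaling turned the balance to 501 and 598 for BAFF and 1041 and 1190 for both at 8 h, 797 and 914 for anti-IgM and 477 and 536 for BAFF at 30 h, and 715 and 630 for both from 8 h to 30 h. Reads over exons, not a scaling, gave 453 and 318 for BAFF and 832 and 608 for both from 8 h to 30 h, 555 and 654 for BAFF and 1483 and 1386 for anti-IgM at 8 h, and 1133 and 1022 for both at 30 h.

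Some list medians outside the random range and some counted genes had the opposite sign. With reads over exons these were TNF family receptors with anti-IgM (0.13) and both (0.12) at 8 h, transitional and marginal zone genes with BAFF at 8 h (0.22), activation surface genes with anti-IgM at 30 h (0.40) and plasma cell genes for both against BAFF at 8 h (-0.10) and against anti-IgM at 30 h (0.02). So did Tyms with anti-IgM at 8 h (-0.33) and with BAFF from 8 h to 30 h (0.45), AC121821.1 (-0.36) and Minos1 (0.05) for both against anti-IgM at 8 h, and Ccl25 (0.16) and Eif2c3 (0.13) at 30 h. With the most abundant transcript, transitional genes with BAFF at 8 h had 0.12 and NF-kappaB genes for both against anti-IgM at 30 h -0.03. Scaling to the same sum gave -0.07 for NF-kappaB and -0.04 for interferon genes in that comparison and -0.02 for B cell identity genes with BAFF from 8 h to 30 h. Of the other list medians 158 moved and 2813 stayed, and of named gene differences 711 moved and 1077 stayed. The reads over exons, held genes, spacing, genes set to 0 and scalings of lists and named genes were chosen after seeing the data. A version with only transcripts that match annotated ones, intended from the start, was not run, because the library files carry no such mark.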

Other observations

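Of 52 markers of other cell types at 1 FPKM or more, 18 were at that level in every library, including Mpeg1, a macrophage pore-forming protein gene (34.8 unstimulated, 61.9 with anti-IgM at 30 h). Emr1 (32.8 unstimulated, 48.2 with BAFF at 30 h) and Lyz2 (16.3, 19.8), 2 further macrophage genes, were low with BAFF at 8 h (11.3 and 2.67) and above the unstimulated value with BAFF at 30 h, but with both stimuli at 30 h they were below it (31.2 and 9.63).

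Both tests of the high macrophage markers in the unstimulated library were chosen after the result was seen. RNA of other cells that was lost in culture could give this pattern: 21 of the 52 markers were at least 2-fold higher there than in any cultured library, against a median of 4 and an upper bound of 8 for random genes. That count largely restates the pattern, so it cannot tell lost cells from lower expression within cells. Scaling of the unstimulated library did not account for the pattern, since all genes together differed by at most 0.13 and the macrophage medians were -2.20 to -2.96. Emr1, Lyz2 and Mpeg1 with BAFF at 30 h do not follow the account of lost cells, nor does Cd68, on the same list and with a close neighbour (98 unstimulated, 321 with anti-IgM and 329 with both at 8 h).

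Of the tests on genes counted between both stimuli and anti-IgM at 8 h but not held, the neighbour test was chosen after the result was seen, and the transcript test was added when that one failed. Division of reads between neighbouring genes did not account for them, as 40.7% of 649 such genes had a neighbour against 40.3% of all compared. Neighbours may still bear on the held genes when BAFF was added to anti-IgM. At 5 FPKM or more, 1.01% of genes with a neighbour were held at 8 h against 0.53% of the others, and 1.27% against 0.57% at 30 h. Against the unstimulated library, genes with a neighbour were held less often than the others in every comparison. A different set of transcripts assembled for the same gene could give the genes not held: 82.4% of them had different numbers of transcripts in the 2 libraries, against 42.5% of all compared and 28.8% of the held genes. The second measure must nearly match FPKM for a gene assembled alike in both libraries. That excess was therefore largely fixed in advance, and the test cannot decide the cause. The test of depth used the balance of all counted genes, 62.1% higher at 20 FPKM or more, which does not bear on the genes not held, so depth was left open.

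All tests of the replication and mitosis genes in the BAFF 30 h library were chosen after the result was seen. Whether RNA of anti-IgM-treated cells mixed into that sample could explain them cannot be told apart: the other genes held higher with anti-IgM at 30 h sat at 0.41 of the anti-IgM difference, and the 48 replication and mitosis genes at 0.48, with a 25th percentile of 0.37. This test was rewritten 3 times with its result known and the answer depended on the version: 13.1% of 534 other genes below a share with a bar of 10 went against mixing, 1.7% in both measures with a bar of 5 went with it, and the same 9 genes with a bar of 5 genes went against it, so the first version is the one reported. Scaling did not account for them, since their median stayed above 0, at 0.93, under the least favourable of the 3 scalings. The random range of -0.33 to -0.07 shifts with the same scaling, so the comparison with it could hardly have come out otherwise. Time in culture, with 0 libraries cultured without a stimulus, likewise cannot be told apart from BAFF.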
